A study of Mus musculus with 24 samples.

How the data were processed

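Transcript abundance was measured on 24 Illumina expression bead arrays of 1 colour, each hybridised with RNA of 1 sample of bone marrow macrophages from female C57BL/6 mice. Per the labels' protocols, RNA was purified on Qiagen RNeasy columns, its quality was read on a Bioanalyser, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Groups were taken from the sample labels, which name the treatment (control or bromodomain inhibitor), the time after lipopolysaccharide (LPS; 0, 1, 2 or 4 h) and a replicate number, giving 8 groups of 3. The design text describes the replicates as biological. The compound, both doses and the length of any pre-treatment are not given in the sources used here.

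The values analysed were the authors' deposited processed values, 1 per probe and array for 25697 probes. The deposited values ran from 5.354 to 15.172 and were therefore read as log2 intensities, since no label or header states their scale. The arrays' ranked values differed by at most 0.004 at 99% of ranks, so the authors' values were read as quantile normalized. The submitters' processing notes name limma, with the version not given. Whether the authors subtracted background is not given in the sources used here. A separate table of non-normalized signals, with 72 value columns, was not used, because its columns carry array positions that no label pairs with samples. The planned background correction, median scaling, detection p-value filters and slide block, which needed that table, were therefore not run, and the deposited processed values, planned as an alternative, became the values analysed.

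Probe names came from the platform annotation: 23978 probes carried 1 gene symbol, 1719 none and 0 several. Symbols were updated through Entrez gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and left 16 identifiers unmatched. No coordinates are given. In place of detection p-values, a floor was set at 6.455 log2 units, the 99th percentile of the values of 1302 olfactory and vomeronasal receptor probes (median 5.887), whose genes macrophages are not known to use. A probe was kept when it lay above the floor on all 3 arrays of at least 1 group, which left 10887 probes. Each gene was represented by its kept probe with the highest mean over all arrays, giving 8201 features, of which 7583 carried a symbol and 618 did not. Features are called genes in counts. At 4 h, kept probes of 2 genes (Cstf3 and Spag9) were called in opposite directions between treatments, and 0 were at the other times.

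Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 24 arrays, with 8 group means and 16 residual degrees of freedom, so that all groups shared 1 estimate of spread per gene. The median residual SD was 0.168 log2 units. The contrasts were inhibitor against control at each time, LPS against 0 h within each treatment, and the difference of the inhibitor effect at 1, 2 or 4 h from that at 0 h. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was a call. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 108 tests (27 lists at 4 times), with camera's estimated correlation and fry beside it. LPS-induced genes were those called and raised by a log2 change of at least 1 in control cells. For the timing comparison, genes raised at 4 h over the mean of both treatments were early when also raised at 1 h and late when not called at 1 h, and the shares lowered at 4 h were compared by Fisher's exact test. The inhibitor effect at 4 h was tested on simulated data of 8201 genes in 5 simulations: 47.6% of genes changed by a log2 value of 0.5, 94% of those changed by 1 and 100% of those changed by 2 were called, and 4.11% of calls were false. In the same simulations no change was put in at 0 h or 1 h, and camera at the preset correlation called 2 of 270 list tests there, both in 1 simulation. The simulated noise was independent between genes, so this number does not cover genes of a list that vary together.

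When every array of a group lay below the floor for a gene, the fold is a bound against the floor and is written "at least". No fold is given when both groups lay below it. No background was subtracted here, so folds of dim genes are understated, and levels near the top of the scale can be compressed by saturation. Named genes with a group mean above 14 were Ccl5, Cxcl10, Cxcl1, Il1b, Cd40, Zfp36, Tnf, Cd69, Il1a, Cmpk2, Nfkbiz and Brd2, so their changes can be understated. Array data give no counts. The number of arrays limits the precision.

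The groups, tests, gene lists, other settings to be tried and the rule for named genes were fixed before the data were examined. The rule took, at each time, the 10 largest called falls and rises whose 3 inhibitor arrays all lay on 1 side of the 3 control arrays, a separation that chance gives in 10% of genes. It also took the 5 largest rises and 3 largest falls with LPS in control cells at each time, up to 2 members per direction of each list, the 5 largest differences of the inhibitor effect from 0 h per direction, and a panel of 20 genes named whatever their result. Of that panel, Il12b has no named probe in the annotation used here, Serpini1 lay below the floor and 1 gene is not reported here.

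Replicate numbers are shared by all groups in the labels. Deviations from group means correlated between same-numbered arrays at 0.563 to 0.847 for inhibitor against control, 0.252 to 0.592 for LPS in control cells and 0.106 to 0.496 for LPS in treated cells, and in 28 of 30 comparisons an array correlated best with the array of its own number. The numbers were therefore taken to pair the samples, from the labels and this check, and the fit with the replicate number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Replicates of a group correlated at 0.977 to 0.9946, and at most 0.317% of values were equal within a pair, so none was counted as a duplicate.

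The other settings fixed beforehand and run were no filter on dim probes, every probe as its own feature, an intensity trend with robust variances, only the arrays compared, the replicate block, an adjusted p under 0.01, array weights, leaving out each array in turn, induced genes taken from the mean of both treatments or at a log2 change of at least 2, timing classes from control cells only, and the estimated correlation. Added after the data were seen were a floor at the 95th percentile, a filter above the floor on all 24 arrays, subtraction of the median receptor probe with an offset of 16, centring on housekeeping genes, cyclic loess, and leaving out all 8 arrays of 1 replicate number.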

Results

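Transcripts were measured on 24 arrays of bone marrow macrophages. The cells had received lipopolysaccharide (LPS), the bacterial cell wall component sensed through Tlr4, for 1, 2 or 4 h, or none (0 h). Each time was sampled with and without an inhibitor of BET bromodomains, the modules with which Brd2 and related proteins bind acetylated lysine. Each of the 8 groups held 3 replicates, which limits the precision. The study asked how the inhibitor alters gene expression after LPS. Changes are log2 differences of group means ± standard error (3 arrays against 3), with limma's adjusted p over 8201 genes. The errors ignore pairing and hold the spread between replicates.

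The time after LPS separated the arrays most. The first principal component held 54.3% of the variance and the second 14.1%. Arrays of replicate 1 lay further from their group means, with a root mean square deviation of 0.20 to 0.25 log2 units over genes, than those of replicate 2 (0.12 to 0.17) or replicate 3 (0.14 to 0.19). Ccl2, a monocyte-attracting chemokine, differed between replicates before LPS, with levels of 8.13, 10.7 and 12.2 in control replicates 1, 2 and 3.

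**Figure D1:**
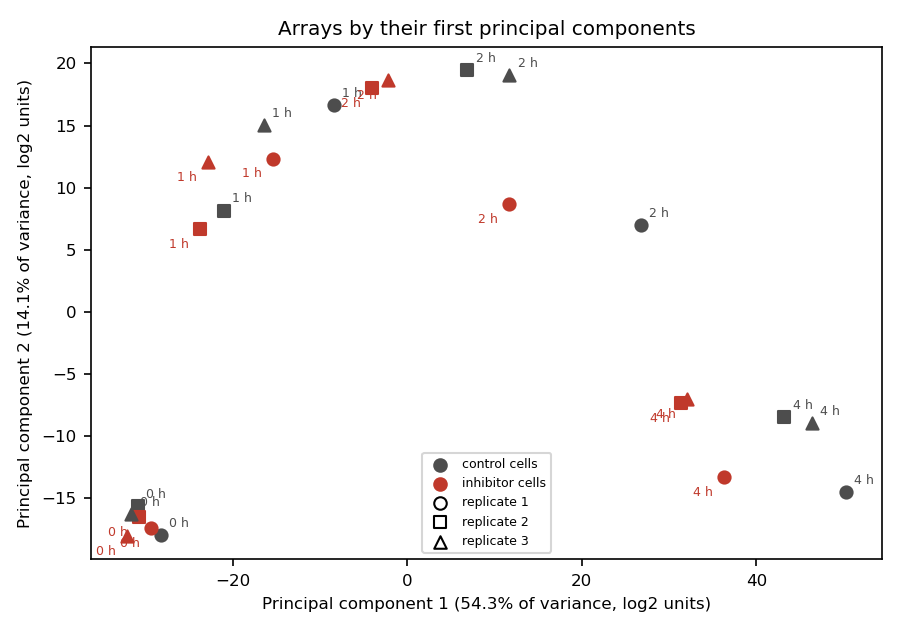
Scores of the 24 arrays on the first 2 principal components of the log2 values, in grey for control and red for inhibitor-treated cells, with circles, squares and triangles for replicates 1, 2 and 3 and the hours of LPS beside each point. The components held 54.3% and 14.1% of the variance, and the times follow one another along the first.

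In control cells LPS raised 29 of 35 primary LPS response genes, 13 of 22 NF-kB members and feedback regulators and 12 of 28 interleukin and cytokine genes at 1 h (33, 16 and 14 adjusted over the list alone). Tnf, the cytokine tumour necrosis factor, rose by 7.87 ± 0.21 at 1 h (adjusted p = 2.69e-16). The neutrophil-attracting chemokine genes Cxcl1 and Cxcl2 rose by 7.82 ± 0.32 and 6.21 ± 0.42, and the interleukin-1 genes Il1a and Il1b by 5.72 ± 0.37 and 5.52 ± 0.45. Nfkbiz and Nfkbia, which encode nuclear and cytoplasmic regulators of NF-kB, rose by 6.84 ± 0.23 and 4.65 ± 0.13. Ifnb1, the interferon beta gene, lay below the floor before LPS and was at least 27.8-fold higher at 1 h (adjusted p = 1.27e-05), at least 53.5-fold at 2 h and at least 7.28-fold at 4 h. Il6 rose by 3.79 ± 0.39 at 1 h, 5.23 ± 0.39 at 2 h and 6.45 ± 0.39 at 4 h. At 4 h the T cell-attracting chemokine gene Ccl5 was up by 7.63 ± 0.36 and Cxcl10 at least 332-fold, beside the surface receptor genes Cd40 (7.61 ± 0.44) and Cd69 (7.13 ± 0.32). Also at 4 h, Cxcl9 was at least 36.2-fold higher, Nos2, the inducible nitric oxide synthase, at least 7.98-fold, and Il12a, a subunit of interleukin-12, at least 6.3-fold. Il10, an anti-inflammatory cytokine gene, was at least 2.1-fold higher at 1 h (adjusted p = 0.000738), was not called at 2 h (adjusted p = 0.13, and 0.0298 without control replicate 1 of that time) and was at least 1.12-fold higher at 4 h (adjusted p = 0.0405). That last call ended without any of control replicates 1 (0.114), 2 (0.0693) and 3 (0.0575) of 0 h, without control replicate 1 of 4 h (0.342) and with no filter on dim probes (0.0748). Brd2 stood at 0.50 ± 0.21 at 1 h (adjusted p = 0.309) and rose by 0.88 ± 0.21 at 2 h and 1.29 ± 0.21 at 4 h.

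A panel of 17 measured genes was named whatever its result. Of these 8 were called higher at 1 h, 13 at 2 h and 15 at 4 h, and none lower. Rises at 2 h and 4 h were 7.55 ± 0.21 and 7.20 ± 0.21 for Tnf, 6.38 ± 0.45 and 6.51 ± 0.45 for Il1b, and 4.24 ± 0.13 and 3.58 ± 0.13 for Nfkbia. Ccl5 rose by 3.82 ± 0.36 at 1 h and 7.14 ± 0.36 at 2 h, and Cxcl10 was at least 34-fold higher at 1 h and 162-fold at 2 h. Cxcl9 was at least 4.26-fold and Il12a at least 1.36-fold higher at 2 h. Neither was called at 1 h (adjusted p = 0.937 and 0.98). The chemokine gene Ccl12 stood at 1.79 ± 0.69 at 1 h (adjusted p = 0.252) and rose by 2.48 ± 0.69 at 2 h (adjusted p = 0.011, and 0.083 without control replicate 1 of 0 h) and 3.31 ± 0.69 at 4 h. Ptgs2, the inducible cyclooxygenase, was not called at 1 h (adjusted p = 0.295). It was at least 1.77-fold higher at 2 h (adjusted p = 0.0145, and 0.109 without control replicate 3 of that time) and 3.34-fold at 4 h. Nos2 was not called at 1 h (adjusted p = 0.984) or 2 h (0.381), nor Ccl2 at 1 h (2.13 ± 0.86, adjusted p = 0.285). Hexim1, an inhibitor of the elongation factor P-TEFb, stood at 0.17 ± 0.26 at 1 h (adjusted p = 0.949) and -0.14 ± 0.26 at 2 h (0.755). Myc, a growth-promoting transcription factor gene, stood at 0.66 ± 0.19 at 1 h (adjusted p = 0.0617). It later lay below the floor in control cells (adjusted p = 0.972 at 2 h and 0.428 at 4 h).

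Falls with LPS at 1 h included Tsc22d3, a glucocorticoid-induced regulator (-1.87 ± 0.32, adjusted p = 0.00105), and the growth arrest gene Gadd45g (-1.59 ± 0.30). Falls at 2 h included the receptor genes Lpar6 (-3.00 ± 0.21) and Cnr2 (-2.84 ± 0.15) and Arhgap25 (-2.90 ± 0.26). At 4 h they included Lhfpl2 (-3.88 ± 0.22), the RNA-binding protein gene Zfp36l1 (-3.83 ± 0.56) and the stress gene Sesn1 (-3.81 ± 0.29). Txnip fell by 1.49 ± 0.35 at 1 h (adjusted p = 0.0179), a call that ended without replicate 1 of the control arrays at 0 h (adjusted p = 0.121) or at 1 h (adjusted p = 0.108). Ccl2 rose by 2.67 ± 0.86 at 2 h (adjusted p = 0.0258) and 2.85 ± 0.86 at 4 h (adjusted p = 0.00862). Without control replicate 1 at 0 h its adjusted p was 0.175 at 2 h and 0.0776 at 4 h, and at 2 h it was 0.0854 and 0.0774 without control replicates 2 and 3 of that time and 0.0502 with no filter on dim probes. Under the block on replicate number the 1 h calls gained Ccl12 (adjusted p = 0.00991), Ccl2 (0.0195), Myc (0.0237, and 0.0275 without control replicate 3 of 0 h, 0.0373 without control replicate 2 of 1 h or 0.0423 after centring on housekeeping genes) and Ptgs2 (0.0384), and the 4 h calls Hexim1 (0.0426, and 0.0341 after background subtraction), which stood at -0.56 ± 0.26 with an adjusted p of 0.0762 otherwise.

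In all, 176 genes rose and 87 fell at 1 h, 821 rose and 1249 fell at 2 h, and 1626 rose and 2687 fell at 4 h, so that 52.6% of the genes were called at the last time. At least 2-fold rises numbered 117, 330 and 643, and at least 2-fold falls 9, 117 and 437. The 1 h total of 263 became 156 without control replicate 1 and 170 without control replicate 3 of that time, and with the replicate number as a block the totals were 518 at 1 h and 3199 at 2 h. The split of calls between rises and falls depended on the scaling of the arrays. Rises made up 66.9%, 39.7% and 37.7% of calls at 1, 2 and 4 h on the deposited values, against 80.2%, 59.9% and 68.6% after centring on housekeeping genes, which moved the median of all genes by 0.11 at 2 h and 0.27 at 4 h. Cyclic loess gave 52.2% at 2 h and 53.4% at 4 h, with a shift of 0.13 at 4 h.

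In inhibitor-treated cells LPS raised Tnf by 7.97 ± 0.21 at 1 h (adjusted p = 2.09e-16), Cxcl1 by 8.04 ± 0.32 and Nfkbia by 4.62 ± 0.13. Il6 rose by 1.5 ± 0.39 at 1 h (adjusted p = 0.0349) and by 5.30 ± 0.39 at 4 h. Ccl5 rose by 7.31 ± 0.36 and Cd40 by 7.48 ± 0.44 at 4 h. Edn1, which encodes the vasoactive peptide endothelin-1, lay below the floor before LPS and was at least 1.59-fold higher at 4 h (adjusted p = 0.000987). These genes were taken from those named in the other comparisons, after their values in treated cells were seen. The LPS response of Il6 did not pass the test of a difference between treatments at 1 h (-2.29 ± 0.55, adjusted p = 0.22), and that of Edn1 did at 4 h, where it was lower in treated cells (adjusted p = 3.2e-07). In total 142 genes rose and 121 fell at 1 h, 607 rose and 861 fell at 2 h, and 1615 rose and 2192 fell at 4 h. The 1 h total of 263 became 139 and 154 without inhibitor replicates 1 and 3 of that time and 160 without inhibitor replicate 3 at 0 h. Totals with the replicate number as a block were 557 at 1 h and 2442 at 2 h. Rises made up 54% of calls at 1 h and 42.4% at 4 h, against 66.8% and 54.8% after centring on housekeeping genes.

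Before LPS, the inhibitor raised 13 genes, all of which encode histones, the proteins around which DNA is wound. Among histone H3 genes, H3c1 rose by 1.67 ± 0.16 (adjusted p = 7.66e-06), H3c4 by 1.54 ± 0.18 and H3c6 by 1.38 ± 0.17. Among histone H4 genes, H4c9 rose by 1.58 ± 0.16, H4c6 by 1.45 ± 0.15, H4c11 by 1.35 ± 0.15, H4c8 by 1.29 ± 0.14, H4c12 by 1.24 ± 0.12 and H4c18 by 1.15 ± 0.16. H3c7 was at least 2.6-fold higher (adjusted p = 0.0137), a call that ended without control replicate 1 (adjusted p = 0.0696) or 2 (adjusted p = 0.121). The others, H2ac6 (1.14 ± 0.16), H2bc8 (0.77 ± 0.10) and H2aw (0.62 ± 0.11), were outside the naming rule and were named after their values were seen. Histone genes resemble one another closely, so a probe can bind transcripts of several copies and single members are uncertain. In the histone list 11 of 41 measured genes were called higher, and 24 when adjusted over the list alone, with a median change of 0.63 and a camera adjusted p of 1.36e-96 (adjusted p = 0.000366 with an estimated correlation). The called H2ac6 and H4c18 were not list members.

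None of the 14 measured genes of the BET and P-TEFb machinery list was called before LPS. Brd2 stood at 0.66 ± 0.21 (adjusted p = 1) and Hexim1 at 0.63 ± 0.26 (adjusted p = 1), with Hexim1 levels of 8.99, 7.75 and 7.33 in inhibitor replicates 1, 2 and 3. Without inhibitor replicate 3 the adjusted p of Brd2 was 0.0262. The list as a whole was called higher by camera (median 0.06, adjusted p = 0.00331, and 0.043 with an estimated correlation). Its adjusted p was 0.15 without inhibitor replicate 1 and 0.0796 with no filter on dim probes. The toll-like receptor list had a camera adjusted p of 0.0821 (adjusted p = 0.4 with an estimated correlation), and 0.0473 with the replicate number as a block, 0.0423 after centring on housekeeping genes and 0.0191 for genes above the floor on all 24 arrays. Without control replicate 1 the primary LPS response list moved from 0.824 to 0.00848 (lower). Without inhibitor replicate 2 the inflammasome and interleukin-1 list moved from 0.13 to 0.0311 (lower). On all arrays these stood at adjusted p = 0.969 and 0.499 with an estimated correlation. Limma called 0 genes lower, with 57 lower and 69 higher at an unadjusted p under 0.05. Blocking on replicate called 23 higher. Without it pairing is ignored, so few calls do not show absence of an effect. None of the 17 measured genes of the panel named whatever its result was called (adjusted p = 1 each). Il1b stood at -0.84 ± 0.45, Il6 at -0.36 ± 0.39, Myc at -0.08 ± 0.19, Tnf at -0.07 ± 0.21, Ccl2 at -0.06 ± 0.86, Ccl12 at 0.01 ± 0.69, Nfkbia at 0.32 ± 0.13 and Ccl5 at 0.34 ± 0.36. Il10, Il12a, Ifnb1, Cxcl9, Cxcl10, Nos2 and Ptgs2 lay below the floor with and without inhibitor.

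At 1 h the inhibitor lowered 5 of 28 interleukin and cytokine genes and raised 19 of 41 histone genes (adjusted p = 0.0539 and 0.0213 with an estimated correlation). Il6, the interleukin-6 gene, fell by 2.65 ± 0.39 (adjusted p = 0.000431), and Edn1 was at least 2.46-fold lower (adjusted p = 0.00024). Flrt3, an adhesion protein gene (-2.60 ± 0.28), Gja1, which encodes the gap junction protein connexin 43 (-1.78 ± 0.22), the orphan receptor gene Gpr85 (-1.64 ± 0.28) and Cd83, a surface protein of activated antigen-presenting cells (-1.62 ± 0.30), also fell. So did the signalling adaptor gene Traf1 (-1.32 ± 0.22) and Rel, which encodes an NF-kB subunit (-1.26 ± 0.19). Rises included Tspoap1 (2.18 ± 0.37, adjusted p = 0.00222), Gadd45g (2.03 ± 0.30), Txnip (1.81 ± 0.35, adjusted p = 0.00705, and 0.0549 without control replicate 1), H3c4 (1.79 ± 0.18), the mitochondrial DNA polymerase subunit gene Polg2 (1.73 ± 0.17) and H3c1 (1.64 ± 0.16), while Matn4, a matrix protein gene, was at least 2.31-fold higher. Brd2 rose by 1.20 ± 0.21 and the heat shock gene Dnajb1 by 1.01 ± 0.16. Tnf stood at 0.03 ± 0.21 (adjusted p = 1), Nfkbia at 0.30 ± 0.13 (0.714), Hexim1 at 0.50 ± 0.26 (0.966) and Myc at 0.03 ± 0.19 (1). Lower in 3 of 3 same-numbered pairs but not called were Ccl2 at -0.34 ± 0.86 (adjusted p = 1), Ccl12 at -1.33 ± 0.69 (0.955), Ptgs2 at -0.39 ± 0.37 (1) and Cxcl10 at -1.20 ± 0.31 (0.0594). Cxcl9 was not called (adjusted p = 1), and Il12a and Nos2 lay below the floor in both treatments. Cxcl10 passed with the replicate number as a block (0.00269), without control replicate 2 (0.015) and without inhibitor replicate 1 (0.0159).

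Several calls at 1 h ended when any 1 of several arrays was left out, while the change stayed negative and lay below 0 in 3 of 3 same-numbered pairs. Ifnb1 fell by 3.01 ± 0.64 (adjusted p = 0.015, and 0.00669 with the replicate number as a block). It stood at -2.25 (0.149) without control replicate 1 and at -2.55 (0.119) and -2.53 (0.14) without inhibitor replicates 2 and 3. Il1b fell by 2.05 ± 0.45 (adjusted p = 0.0177, and 0.0111 with the block). It stood at -1.75 (0.15) and -1.92 (0.103) without control replicates 1 and 3 and at -1.62 (0.15) and -2.00 (0.0892) without inhibitor replicates 2 and 3. Ccl5 fell by 1.69 ± 0.36 (adjusted p = 0.0142, and 0.00341 with the block). It stood at -1.20 (0.125) without control replicate 1 and at -1.36 (0.119) and -1.54 (0.103) without inhibitor replicates 2 and 3. Il10 was at least 2.1-fold lower (adjusted p = 0.00716, and 0.00343 with the block), with 0.0606 without control replicate 3 and 0.0544 without inhibitor replicate 1, and was not called at 2 h (adjusted p = 0.598) or 4 h (0.327). Of the 33 named genes called at 1 h, 16 lost the call without some 1 array. In total 64 genes were called lower and 43 higher. The lower count became 32 and 42 without control replicates 1 and 3 and 38 and 37 without inhibitor replicates 2 and 3, and the higher count 22 without control replicate 1 and 26 without inhibitor replicate 3. With the replicate number as a block 141 were called lower and 66 higher.

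Among the lists at 1 h, 4 of 26 secondary LPS response genes fell (7 fell and 1 rose when adjusted over the list alone, median -0.22), with a camera adjusted p of 2.31e-07 (adjusted p = 0.0683 with an estimated correlation). Of 28 interleukin and cytokine genes 5 fell (6 adjusted over the list alone, median -0.26), with a camera adjusted p of 1.3e-08 (adjusted p = 0.0539 with an estimated correlation). Of 22 NF-kB members and feedback regulators 2 fell (9 adjusted over the list alone), with a camera adjusted p of 6.4e-09 (adjusted p = 0.0657 with an estimated correlation). Of 10 inflammasome and interleukin-1 genes 2 fell (3 adjusted over the list alone), with a camera adjusted p of 8.39e-05 (adjusted p = 0.0683 with an estimated correlation). Chemokines (1 of 18, and 4 adjusted over the list alone) and the toll-like receptor pathway (0 of 28, and 1 adjusted over the list alone) were lower at camera adjusted p values of 0.000976 and 4.97e-05 (adjusted p = 0.0742 and adjusted p = 0.0539 with an estimated correlation). Interferons and their receptors (1 of 6, and 2 adjusted over the list alone) were lower at 0.00396 (adjusted p = 0.0539 with an estimated correlation), which became 0.108 without control replicate 1 and 0.144 for genes above the floor on all 24 arrays. Histone genes were higher, with 19 of 41 called (23 adjusted over the list alone, median 0.62), at 7.2e-40 (adjusted p = 0.0213 with an estimated correlation). Heat shock proteins (2 of 11, and 3 adjusted over the list alone) were higher at 0.0025 (adjusted p = 0.043 with an estimated correlation), which became 0.15 for genes above the floor on all 24 arrays. Unfolded protein and amino acid stress genes (1 of 21 higher, and 1 higher and 1 lower adjusted over the list alone) were higher at 0.00128 (adjusted p = 0.0539 with an estimated correlation). Primary LPS response genes had 3 lower and 2 higher of 35 (4 and 5 adjusted over the list alone) and a camera adjusted p of 0.662, and type I interferon stimulated genes 0 of 50 (1 lower adjusted over the list alone) and 0.2. The latter list passed as lower without inhibitor replicate 1 (4.35e-05), control replicate 2 (0.008) or control replicate 3 (0.0162), and anti-inflammatory feedback genes (3 of 19 lower, and 4 lower and 1 higher adjusted over the list alone) moved from 0.148 to 0.0438 without control replicate 2. On all arrays these lists stood at adjusted p = 0.937 and adjusted p = 0.433 with an estimated correlation.

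At 2 h the inhibitor lowered 13 of 26 secondary LPS response genes and 20 of 50 type I interferon stimulated genes (adjusted p = 0.033 and 0.157 with an estimated correlation). Edn1 fell by 4.17 ± 0.22 (adjusted p = 1.73e-10) and Fpr2, a receptor for formyl peptides, fell by 3.30 ± 0.20 (adjusted p = 1.08e-09). H2-M2, a non-classical class I histocompatibility gene (-2.98 ± 0.45), Ifnb1 (-2.85 ± 0.64, adjusted p = 0.0077), Calhm6 (-2.75 ± 0.27), Ch25h, the cholesterol 25-hydroxylase (-2.63 ± 0.60), the interferon-induced gene Ifit3 (-2.56 ± 0.55) and Rgs1, a regulator of G protein signalling (-2.53 ± 0.46), fell as well. Il6 fell by 1.82 ± 0.39 (adjusted p = 0.0048), Cxcl10 fell by 1.69 ± 0.31, Traf1 fell by 1.62 ± 0.22 and Irak2, a kinase of toll-like receptor signalling, fell by 1.29 ± 0.21. Il12a was at least 1.36-fold lower (adjusted p = 0.00208). Tnf (-0.24 ± 0.21, adjusted p = 0.62), Il1b (-0.59 ± 0.45, 0.56), Ccl5 (-0.48 ± 0.36, 0.549), Ptgs2 (-0.36 ± 0.37, 0.69), Ccl2 (-0.12 ± 0.86, 0.962), Nos2 (0.644) and Myc (0.36) were not called. Ccl12 (-2.28 ± 0.69, 0.0517) was not called either, but passed with the replicate number as a block (0.000653), without inhibitor replicate 2 (0.0392), after centring on housekeeping genes (0.0412) and after cyclic loess (0.0389). Rises included Tspoap1 (2.66 ± 0.37, adjusted p = 9.16e-05), the immediate early gene Fosb (1.93 ± 0.38), H3c4 (1.84 ± 0.18), Csrnp2 (1.62 ± 0.24), the ceramidase gene Acer2 (1.62 ± 0.17) and the transcription factor gene Klf2 (1.60 ± 0.27), with Matn4 at least 3.56-fold and H3c1 at least 3.11-fold higher. Brd2 rose by 1.44 ± 0.21, Hexim1 by 1.14 ± 0.26 (adjusted p = 0.00806), Dnajb1 by 1.14 ± 0.16 and Cdkn1a, a cell cycle inhibitor gene, by 0.76 ± 0.16.

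In total 346 genes were called lower and 223 higher at 2 h, of which 108 and 44 changed at least 2-fold. The lower count became 222 without control replicate 1 and 217 without inhibitor replicate 3, and the higher count 143 without control replicate 1. Blocking on the replicate number gave 637 lower and 516 higher. Rises made up 39.2% of calls, and 27.9% after centring on housekeeping genes. Of the 52 named genes called at 2 h, 19 lost the call without some 1 array. Cxcl9 fell by 1.83 ± 0.54 (adjusted p = 0.0436), with 0.206 without control replicate 1, 0.166 and 0.169 without inhibitor replicates 2 and 3, and 0.0795 with no filter on dim probes. Nfkbia rose by 0.44 ± 0.13 (adjusted p = 0.0474), with 0.225 and 0.0738 without control replicates 1 and 3 and 0.151 without either inhibitor replicate 2 or inhibitor replicate 3. That call also ended under 6 other settings of the filter, background, scaling and probe choice, at 0.0511 to 0.0683.

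Of 50 type I interferon stimulated genes 20 fell at 2 h (33 adjusted over the list alone, median -0.88), with a camera adjusted p of 9.22e-22 (adjusted p = 0.157 with an estimated correlation). Of 26 secondary LPS response genes 13 fell and 1 rose (16 and 1 adjusted over the list alone, median -0.97), at 8.76e-14 (adjusted p = 0.033 with an estimated correlation). Of 28 interleukin and cytokine genes 10 fell (12 lower and 2 higher adjusted over the list alone), at 8.91e-09 (adjusted p = 0.0539 with an estimated correlation). The toll-like receptor pathway (4 of 28 lower, and 5 adjusted over the list alone) stood at 7.05e-05 (adjusted p = 0.0539 with an estimated correlation) and the NF-kB list (5 of 22 lower and 1 higher, and 7 and 1 adjusted over the list alone) at 0.000194 (adjusted p = 0.234 with an estimated correlation). Inflammasome and interleukin-1 genes (4 of 10 lower, and 5 adjusted over the list alone) stood at 0.000211 (adjusted p = 0.0756 with an estimated correlation). Chemokines (3 of 18 lower, and 4 adjusted over the list alone) stood at 0.014 (adjusted p = 0.191 with an estimated correlation), and at 0.0538 after centring on housekeeping genes and 0.116 for genes above the floor on all 24 arrays. Interferons and their receptors (1 of 6 lower, and 3 adjusted over the list alone) stood at 0.0179 (adjusted p = 0.071 with an estimated correlation), and at 0.0711 without control replicate 2 and 0.283 above that floor. Of 41 histone genes 23 rose (27 adjusted over the list alone, median 0.72), at 1.49e-21 (adjusted p = 0.0539 with an estimated correlation), and of 11 heat shock genes 3 rose (3 adjusted over the list alone), at 0.0162 (adjusted p = 0.0539 with an estimated correlation, and adjusted p = 0.158 above that floor). With the replicate number as a block the macrophage transcription factors (2 of 25 lower and 1 higher, and 4 and 1 adjusted over the list alone) moved from 0.0821 to 0.0251 and the cell cycle genes (1 of 25 lower, and 0 adjusted over the list alone) from 0.0875 to 0.0424. Without the block they stood at adjusted p = 0.102 and adjusted p = 0.784 with an estimated correlation. The former passed also without inhibitor replicate 2 (0.0344) and with no filter on dim probes (0.025), and the latter without control replicate 1 (0.00033) or inhibitor replicates 2 (0.0366) or 3 (0.00373). Anti-inflammatory feedback genes (4 lower and 1 higher of 19, and 6 and 1 adjusted over the list alone) moved from 0.145 (adjusted p = 0.426 with an estimated correlation) to 0.0295 without control replicate 1. Primary LPS response genes, with 3 lower and 3 higher of 35 (3 and 6 adjusted over the list alone), were not called (0.863).

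At 4 h the inhibitor lowered 19 of 26 secondary LPS response genes, 13 of 28 interleukin and cytokine genes and 21 of 50 type I interferon stimulated genes (adjusted p = 0.0213, 0.0539 and 0.401 with an estimated correlation). Edn1 fell by 3.83 ± 0.22 (adjusted p = 3.65e-10), H2-M2 fell by 3.62 ± 0.45, Fpr2 fell by 3.51 ± 0.20 and Rgs1 fell by 3.21 ± 0.46. Among chemokine genes Ccl12 fell by 2.95 ± 0.69 and Cxcl9 fell by 2.89 ± 0.54, and among cytokine genes Il12a fell by 2.76 ± 0.18 (adjusted p = 1.72e-09), Il1rn, the interleukin-1 receptor antagonist, fell by 2.02 ± 0.36 and Il6 fell by 1.52 ± 0.39. Ifnb1 was at least 7.28-fold lower (adjusted p = 0.00149) and the interferon-induced GTPase gene Tgtp1 at least 3.99-fold lower. Fcgr1, a high-affinity receptor for immunoglobulin G (-2.73 ± 0.18), complement factor gene Cfb (-2.53 ± 0.27), Isg20 (-2.41 ± 0.22) and Nos2 (-1.37 ± 0.20) fell. The transcription regulator genes Irf8 (-2.00 ± 0.30), Batf2 (-1.95 ± 0.33) and Ciita, the regulator of class II histocompatibility genes (-1.30 ± 0.17), were lower, as were the receptor genes Tlr3 (-1.36 ± 0.17) and Tlr6 (-1.23 ± 0.12). Tnf (-0.17 ± 0.21, adjusted p = 0.619), Ccl5 (0.02 ± 0.36, 0.982), Ccl2 (0.09 ± 0.86, 0.963), Cxcl10 (-0.46 ± 0.31, 0.321), Il1b (-0.86 ± 0.45, 0.189) and Myc (0.382) were not called. Ptgs2 fell by 1.26 ± 0.37 (adjusted p = 0.0186), with 0.122 without control replicate 3 and 0.0872 and 0.075 without inhibitor replicates 1 and 2.

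Rises at 4 h included Tspoap1 (2.49 ± 0.37), the kinase gene Mknk2 (2.44 ± 0.21, adjusted p = 6.87e-08), the spliceosomal RNA gene Rnu6 (2.39 ± 0.22), H3c6 (2.29 ± 0.17), H3c4 (2.12 ± 0.18) and the thiamine transporter gene Slc19a2 (1.95 ± 0.18), with H3c1 at least 3.33-fold higher. Klf2 rose by 1.84 ± 0.27, Agfg2 by 1.75 ± 0.13, Hexim1 by 1.75 ± 0.26 (adjusted p = 5.05e-05), Sesn1 by 1.5 ± 0.29, Brd2 by 1.33 ± 0.21 and the amino acid transporter gene Slc7a5 by 1.31 ± 0.21. Sqle, an enzyme of sterol synthesis (1.02 ± 0.19), the chaperone genes Dnajb9 (0.94 ± 0.12) and Hsp90aa1 (0.83 ± 0.11), and Nfkbia (0.59 ± 0.13) also rose. In total 840 genes were called lower and 1034 higher, or 22.9% of those tested, of which 195 and 85 changed at least 2-fold. Of the 62 named genes called at 4 h, 14 lost the call without some 1 array. Blocking on the replicate number gave 1262 lower and 1613 higher. Which direction held more calls depended on the scaling. Rises made up 55.2% of calls on the deposited values, 29.1% after centring on housekeeping genes, which moved the median of all genes from 0.04 by -0.13, and 40.7% after cyclic loess.

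**Figure D2:**
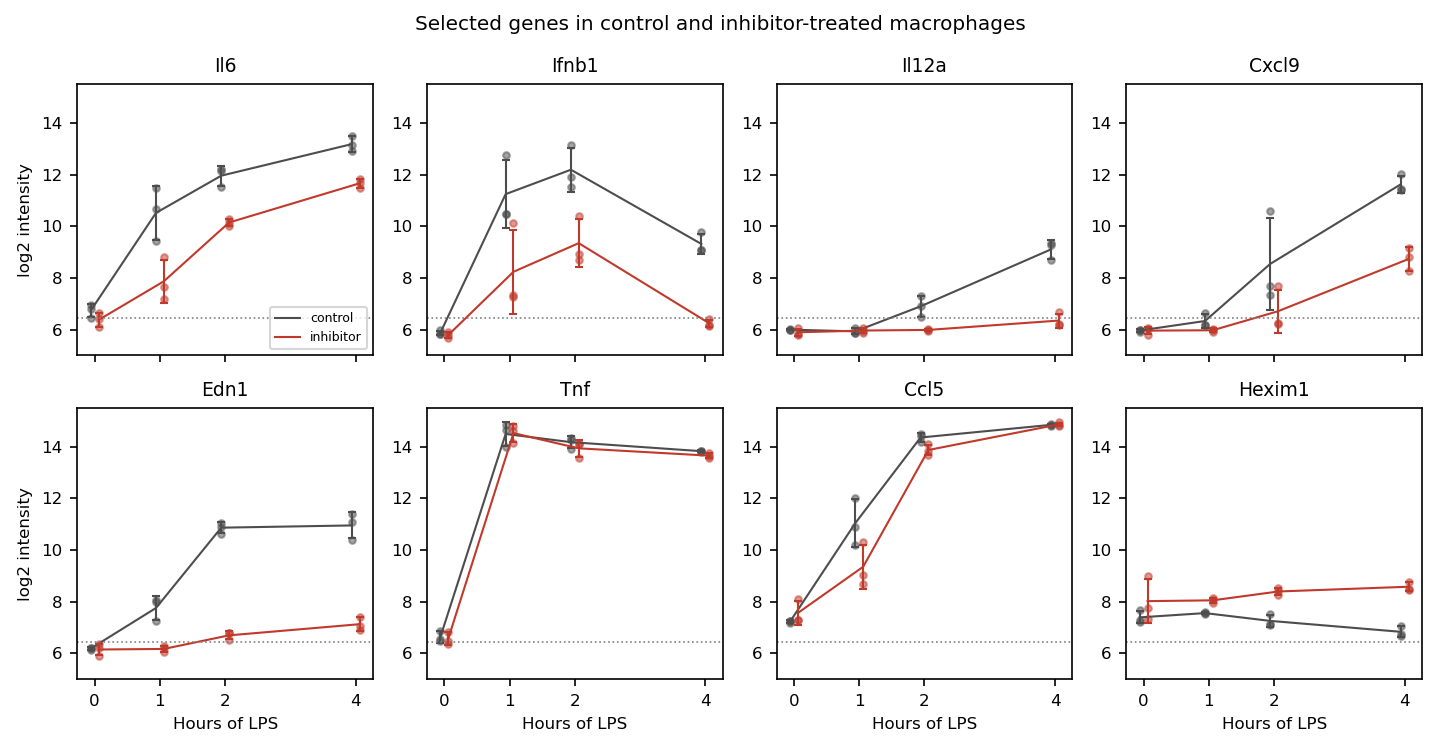
Log2 levels of Il6, Ifnb1, Il12a, Cxcl9, Edn1, Tnf, Ccl5 and Hexim1 against hours of LPS, with points for arrays, lines for group means, bars for the SD (n = 3) and a dotted line at the floor of 6.455. At 4 h Edn1 differed by -3.83 and Il12a by -2.76 between inhibitor and control, while Tnf and Ccl5 differed by -0.17 and 0.02.

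**Figure D3:**
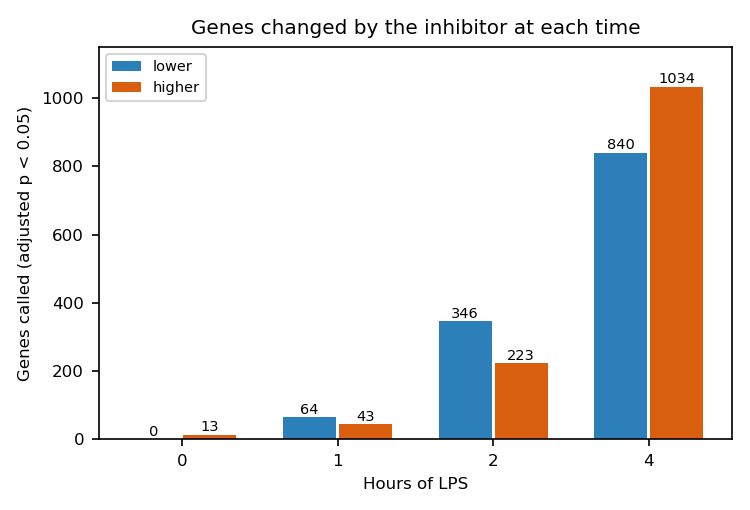
Numbers of genes called lower and higher with the inhibitor against control at 0, 1, 2 and 4 h of LPS, at an adjusted p under 0.05. The counts ran from 0 lower and 13 higher at 0 h to 840 lower and 1034 higher at 4 h.

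Of 26 secondary LPS response genes 19 fell at 4 h (20 adjusted over the list alone, median -1.34), with a camera adjusted p of 3.5e-16 (adjusted p = 0.0213 with an estimated correlation). Of 50 type I interferon stimulated genes 21 fell (25 adjusted over the list alone, median -0.58), at 3.47e-10 (adjusted p = 0.401 with an estimated correlation). Of 28 interleukin and cytokine genes 13 fell (17 adjusted over the list alone, median -0.91), at 2.03e-09 (adjusted p = 0.0539 with an estimated correlation). Inflammasome and interleukin-1 genes (6 of 10 lower, and 8 adjusted over the list alone) stood at 1.1e-05 (adjusted p = 0.0539 with an estimated correlation). The toll-like receptor pathway (8 of 28 lower and 1 higher, the same numbers adjusted over the list alone) stood at 0.0186 (adjusted p = 0.234 with an estimated correlation). Macrophage transcription factors (9 of 25 lower and 1 higher, the same numbers adjusted over the list alone) stood at 0.0214 (adjusted p = 0.0539 with an estimated correlation), and at 0.121 after centring on housekeeping genes. Chemokines (3 of 18 lower, and 3 adjusted over the list alone) stood at 0.0331 (adjusted p = 0.254 with an estimated correlation). That call ended without control replicate 1 (0.0507) or 3 (0.0515), without inhibitor replicate 2 (0.0751), after centring on housekeeping genes (0.161), after cyclic loess (0.0748) and for genes above the floor on all 24 arrays (0.158). Of 41 histone genes 28 rose (29 adjusted over the list alone, median 0.88), at 2.34e-16 (adjusted p = 0.0683 with an estimated correlation). Of 11 heat shock genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), at 0.0307 (adjusted p = 0.0686 with an estimated correlation), a call that ended without inhibitor replicate 1 (0.0612) or control replicate 2 (0.088) and above that floor (0.12).

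None of the other lists was called by camera at 4 h. Members called included 7 higher and 1 lower of 21 unfolded protein and amino acid stress genes (adjusted p = 0.186), 4 higher of 14 genes of the BET and P-TEFb machinery (0.0821), 4 lower of 15 class I antigen presentation genes (0.13), and 3 higher and 1 lower of 16 p53 target genes (0.196). Sterol synthesis had 3 higher and 1 lower of 18 (0.196), the LXR and lipid efflux list 1 lower of 11 (0.576), anti-inflammatory genes 4 lower and 2 higher of 19 (0.302), NF-kB regulators 2 lower and 1 higher of 22 (0.186), interferons and their receptors 1 lower of 6 (0.148), primary LPS response genes 3 lower and 4 higher of 35 (0.863), glycolysis and hypoxia 1 lower of 19 (0.824) and housekeeping genes 1 higher of 10 (0.498). Cell cycle genes had 2 lower of 25 at 0.0875, and 0.0219 with the replicate number as a block, 0.0101 without control replicate 1 and 0.0238 without inhibitor replicate 3, and class I antigen presentation reached 0.0292 without inhibitor replicate 1. On all arrays and without the block these lists stood at adjusted p = 0.784 and 0.547 with an estimated correlation. With no filter on dim probes the BET and P-TEFb machinery (0.0241), sterol synthesis (0.0434) and the unfolded protein and amino acid stress list (0.0204) passed as higher. With the filter and an estimated correlation they stood at adjusted p = 0.123, 0.67 and 0.401. Adjusted over the list alone these numbers of called members were the same, apart from primary LPS response genes (6 lower and 6 higher), p53 targets (1 lower and 4 higher), and cell cycle, glycolysis and hypoxia, and housekeeping genes (0 each). Among cell type markers, 4 of 22 macrophage identity genes (0.186), 2 of 10 class II and dendritic cell genes (0.196) and 1 of 6 neutrophil and myeloid precursor genes, Gfi1 (0.225), were lower. None of 6 erythroid and mast cell markers (0.945) or 3 stromal markers (0.926) was called, and the single measured lymphocyte marker stood at 0.24. For erythroid and mast cell markers the median (0.03) and the mean (-0.04) differed in sign, as they did at 2 h for glycolysis and hypoxia (0.07 and -0.04) and sterol synthesis (0.01 and -0.02).

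**Figure D4:**
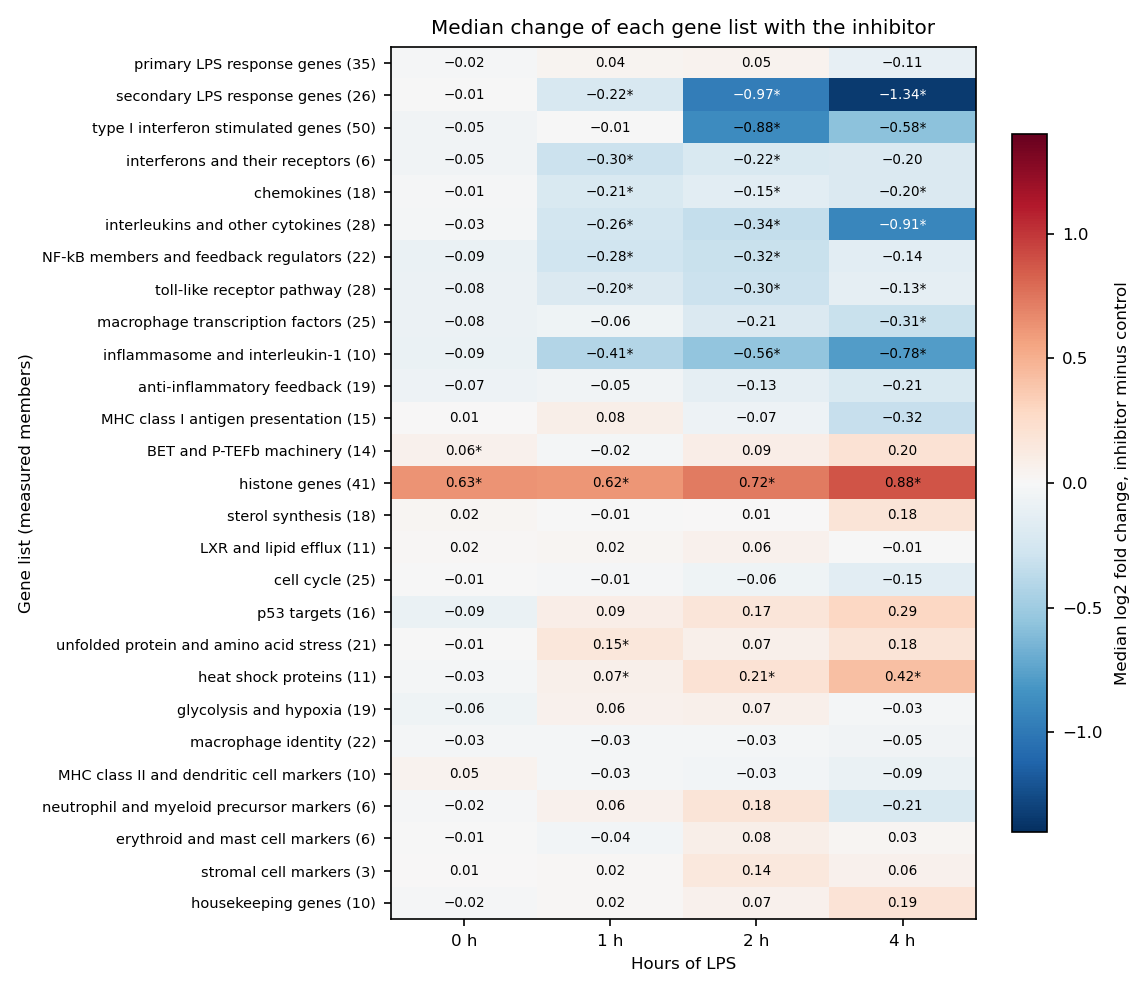
Median log2 change of each gene list with the inhibitor against control at 0, 1, 2 and 4 h of LPS, with a star where camera's adjusted p was under 0.05. Secondary LPS response genes reached -1.34 at 4 h, and histone genes ran from 0.63 at 0 h to 0.88 at 4 h.

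Camera called 31 of the 108 list tests at its preset correlation and 35 with the replicate number as a block, and fry, which asks whether a list's genes move one way on balance, called 38. With an estimated correlation 6 calls held, namely histone genes at 0 and 1 h, secondary LPS response genes at 2 and 4 h, the BET and P-TEFb machinery at 0 h and heat shock proteins at 1 h. Other splits of the 6 arrays of a time called up to 5 lists at 0 h, 12 at 1 h, 10 at 2 h and 8 at 4 h, against 2, 10, 10 and 9 for the real split when adjusted over the lists of each time. The 3 other splits that part all 3 same-numbered pairs called up to 2, 10, 10 and 8 lists. At 0, 1 and 2 h the number of lists called was thus no larger than in some other split, and equal to the highest among those that part all pairs.

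Genes that LPS raised in control cells were lower with the inhibitor more often than other genes. At 1 h 30 of 117 induced genes (25.6%, 95% Wilson interval 18.6 to 34.2) were called lower, with 2 higher, against 0.421% of the other genes. At 2 h these were 127 of 330 (38.5%, 33.4 to 43.8), with 4 higher, against 2.78%. At 4 h they were 295 of 643 (45.9%, 42.1 to 49.7), with 15 higher, against 7.21%. The median change of the induced genes was -0.59 at 1 h, -0.59 at 2 h and -0.52 at 4 h. The intervals treat genes as independent, which they are not. Since induced genes were chosen on the control arrays that also enter the comparison, unchanged groups were simulated against them 20 times, and the highest share was 0.735% at 1 h, 0.282% at 2 h and 0% at 4 h. With induced genes taken from the mean of both treatments the shares were 12.8%, 30.5% and 37.5%, with medians of -0.22, -0.38 and -0.41. Called higher were then 7 of 117 (5.98%), 10 of 262 (3.82%) and 19 of 518 (3.67%), against 1.71%, 1.21% and 2.33% of the genes induced in control cells. The 1 h share was 14.8% without control replicate 1 and 14.5% and 15.7% without inhibitor replicates 2 and 3.

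Genes raised at 4 h but not called at 1 h were lowered more often at 4 h than those raised at both times. Of 76 early genes 13 (17.1%) were lower, and of 388 late genes 168 (43.3%), a difference of 26.2 percentage points (two-sided Fisher's exact test across genes, p = 1e-05). Genes are not independent here. Classes from both treatments can lose early genes lowered at 1 h, and falls of bright genes can be compressed. With classes from control cells alone the shares were 33.3% and 49.1% (difference 15.8, Fisher's exact p = 0.00932). The difference was 15.4 in a fit of only the arrays compared (Fisher's exact p = 0.0181) and 15.3 at an adjusted p under 0.01 (p = 0.00523). It was 16.4 without control replicate 1 of 4 h (Fisher's exact p = 0.00521) and 17.0 without inhibitor replicate 2 of 4 h (p = 0.00257). It was 13.5 without all arrays of replicate 3 (Fisher's exact p = 0.00573) and 8.97, no longer passing, without those of replicate 2 (p = 0.0905).

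Tested directly, the inhibitor effect after LPS differed from that before LPS in 2 genes at 1 h (0 lower by limma, with 104 at an unadjusted p under 0.05, and 2 higher), 72 at 2 h (53 and 19) and 658 at 4 h (316 and 342). At 1 h these were Polg2 (1.61 ± 0.24, adjusted p = 0.00754) and Lsmem1 (higher, adjusted p = 0.00754). No size is given for Lsmem1, Edn1, Matn4 and Acer2 here, because in each at least 1 of the 4 groups lay wholly below the floor. Edn1 lay below it in both groups at 0 h, where no lowering could show, so its calls cannot show dependence on LPS. At 2 h the effect was lower on Edn1 (adjusted p = 1.33e-07), Fpr2 (-3.32 ± 0.28, adjusted p = 5.34e-07), Calhm6 (-2.75 ± 0.38) and Gja1 (-2.21 ± 0.31), and higher for Matn4 (adjusted p = 0.00141) and Acer2 (adjusted p = 0.00206). At 4 h the lower side included Edn1 (adjusted p = 3.2e-07), H2-M2 (-3.69 ± 0.64) and Fpr2 (-3.53 ± 0.28), and the higher side Mknk2 (2.35 ± 0.30), Rnu6 (2.31 ± 0.32) and Slc19a2 (1.82 ± 0.25). The 1 h count became 7 without inhibitor replicate 1 of 0 h and 14 without control replicate 2 of 1 h. The 2 h count became 122 without inhibitor replicate 1 of 0 h, 34 without control replicate 1 and 28 without inhibitor replicate 3 of 2 h, 28 and 31 without control replicates 2 and 3 of 0 h, and 23 and 33 without inhibitor replicates 2 and 3 of 0 h. With the replicate number as a block the counts were 13, 246 and 1424.

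Calls at different times shared more genes than independent lists would. Of the genes lower at 2 h, 229 were also lower at 4 h, where independent lists would share 35.4, and 193 were higher at both times, where independent lists would share 28.1. Between 1 h and 2 h, 44 were lower and 36 higher at both (2.7 and 1.17 for independent lists). Between 1 h and 4 h, 29 of the 64 genes lower at 1 h (45.3%) were lower at both and 33 higher at both (6.56 and 5.42 for independent lists). Pelo and Zfp715 were called in opposite directions at these times, and were named after their values were seen. Pelo stood at -0.53 ± 0.12 at 1 h (adjusted p = 0.025) and 0.50 ± 0.12 at 4 h (adjusted p = 0.00447), and Zfp715 at -0.55 ± 0.12 (0.0148) and 0.34 ± 0.12 (0.0378). Both 1 h calls ended without some 1 array, at up to 0.154 for Pelo and 0.107 for Zfp715, as did the 4 h call of Zfp715 (up to 0.233). Centring on housekeeping genes ended the 1 h call of Pelo (0.0695) and both 4 h calls (0.0526 and 0.173). The 229 became 148 and the 193 became 123 without control replicate 1 of 2 h. They were 445 and 412 with the replicate number as a block. Genes shared by 1 h and 2 h became 22 lower and 19 higher without control replicate 1 of 1 h, and 26 and 23 without inhibitor replicate 3 of 1 h. Without inhibitor replicate 2 of 1 h 29 were lower, and with the block 94 and 58. Those shared by 1 h and 4 h became 16 and 14 without control replicate 1, 19 and 20 without inhibitor replicate 3 of 1 h, and 64 and 52 with the block. These comparisons use different arrays and share no controls. Of the 13 genes called before LPS, 9 were also called higher at 1 h, 12 at 2 h and 13 at 4 h.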

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

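The tests of cross-hybridisation, of S phase genes, of shared control arrays and of both explanations for replicate 1, the check on genes below the top of the scale, the medians of H2A genes and the estimated correlation for the list tests of the difference from 0 h were chosen after the result was seen.

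The inhibitor effect after LPS differed from the effect before LPS, by a test of the difference itself, in 2 genes at 1 h, 72 at 2 h and 658 at 4 h. Where a group of the comparison lay wholly below the floor, only the direction and limma's adjusted p are given. At 1 h these were Polg2 (1.61) and Lsmem1 (higher, adjusted p = 0.00754). At 2 h the lower side held Fpr2 -3.32, H2-M2 -3.05, Calhm6 -2.75, Gja1 -2.21 and Edn1 (adjusted p = 1.33e-07), and the higher Dyrk3 1.15, Rbm15 1.13, Matn4 (adjusted p = 0.00141), Acer2 (adjusted p = 0.00206) and Hapln3 (adjusted p = 0.0349). At 4 h they were H2-M2 -3.69, Fpr2 -3.53, Edn1 (adjusted p = 3.2e-07), Cxcl9 (adjusted p = 0.0227) and Ifnb1 (adjusted p = 0.0471) on the lower side and Mknk2 2.35, Rnu6 2.31, Slc19a2 1.82, Agfg2 1.71 and Klf2 1.71 on the higher. Settings of the filter, probes, background and scaling ended 3 of these calls: Ifnb1 at 4 h with every probe as its own feature (adjusted p = 0.0515), the floor at the 95th percentile (0.0532) and no filter on dim probes (0.0866), Cxcl9 at 4 h with background subtraction (0.0521), and Hapln3 at 2 h with background subtraction (0.0539), centring on housekeeping genes (0.052) and no filter (0.0526). Fitting only the arrays compared ended Polg2 and Lsmem1 at 1 h (0.232 each) and H2-M2 (0.0711), Rbm15 (0.112), Dyrk3 (0.0546) and Hapln3 (0.0651) at 2 h. Leaving out all arrays of replicate 3 ended both calls at 1 h, those at 2 h other than Fpr2 and Edn1, and Klf2, Cxcl9 and Ifnb1 at 4 h (0.0765 to 1). Leaving out all arrays of replicate 2 ended the same calls apart from Dyrk3 and Matn4, and H2-M2 at 4 h (0.055 to 0.748), and leaving out those of replicate 1 ended Lsmem1 (0.0521). Leaving out 1 array ended several: Ifnb1 at 4 h for each of the 12 arrays (adjusted p 0.0631 to 0.102), and Cxcl9 at 4 h without control replicate 1 (0.0572) or inhibitor replicate 3 (0.0643) of 4 h. At 2 h H2-M2 lost it without control replicates 2 (0.0783) or 3 (0.0774) of 0 h, control replicate 1 of 2 h (0.0745), inhibitor replicate 2 of 0 h (0.0845) or inhibitor replicate 3 of 2 h (0.0848). Dyrk3 lost it without control replicate 2 of 0 h (0.0795), control replicate 1 of 2 h (0.065), inhibitor replicate 3 of 0 h (0.0635) or of 2 h (0.0741). Rbm15 lost it without any 1 of 7 arrays (adjusted p 0.0538 to 0.0866) and Hapln3 without any 1 of 9 (0.0579 to 0.115), of 12 compared.

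The same test on gene lists called 25 of 81 list comparisons at the preset correlation and 4 with an estimated one. It gave camera adjusted p values at 1 h of 1.92e-06 for secondary LPS response genes, 2.41e-07 for interleukins and other cytokines, 6.11e-06 for NF-kB members and feedback regulators, 0.00074 for chemokines, 0.0096 for the inflammasome and interleukin-1 list, 0.0169 for the toll-like receptor pathway and 0.0254 for interferons and their receptors, all lower after LPS. With an estimated correlation none of these 7 calls held, at adjusted p = 0.126, 0.108, 0.148, 0.108, 0.248, 0.248 and 0.126 in that order. Heat shock proteins (0.000161) and unfolded protein and amino acid stress genes (0.00426) were higher, at adjusted p = 0.0149 and 0.108 with an estimated correlation. At 2 h the lower lists were type I interferon stimulated genes (2.32e-22), secondary LPS response genes (3.01e-16), interleukins and other cytokines (5.17e-09), NF-kB members and the toll-like receptor pathway (0.0019 each), the inflammasome list (0.00322), chemokines (0.00542) and interferons and their receptors (0.0345), and heat shock proteins (0.00168) were higher. With an estimated correlation secondary LPS response genes (adjusted p = 0.0149) and heat shock proteins (0.0304) kept the call, and the others did not, at adjusted p = 0.15 for interferon stimulated genes, 0.0915 for cytokines, 0.337 for NF-kB members, 0.129 for the toll-like receptor pathway and for interferons and their receptors, 0.167 for the inflammasome list and 0.148 for chemokines. At 4 h secondary LPS response genes (4.52e-17), type I interferon stimulated genes (3.98e-09), interleukins and other cytokines (4.44e-09), the inflammasome list (0.000161) and chemokines (0.0294) were lower, and heat shock proteins (0.0157) and histone genes (0.0254) higher. With an estimated correlation secondary LPS response genes kept the call (adjusted p = 0.0149), and the others did not, at adjusted p = 0.404, 0.0915, 0.108 and 0.267 for the lower lists and 0.0921 and 0.655 for the higher in that order.

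Of 41 histone genes 11, 19, 23 and 28 were called higher with the inhibitor at 0, 1, 2 and 4 h (adjusted p = 0.000366, 0.0213, 0.0539 and 0.0683 with an estimated correlation), and of the 15 H2A genes among them 1, 1, 2 and 4, with H2A medians of 0.50, 0.04, -0.01 and -0.01. More cells in S phase is argued against, since the median change of S phase genes before LPS was -0.024 (14 of 16 genes measured, SD 0.11), against 0.63 for histone genes. Cross-hybridisation among close copies within families stays open, since probes of 1 family can follow the same transcript. Before LPS, 2 families had more than 1 called list gene (4 H3, 5 H4, 1 H2A and 1 H2B gene), beside H2ac6 and H4c18 off the list. A change in 3' end processing or poly(A) tails of replication-dependent histone transcripts, which the labelling would pick up, stays open too: at 4 h replication-dependent genes stood at 0.89 (35 genes) and replacement genes at 0.18 (5 genes), a difference of 0.71 with a two-sided permutation p of 0.153 that so few replacement genes cannot settle. A direct effect of the inhibitor on histone gene expression may also hold and was not tested.

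LPS-induced genes were lower with the inhibitor at 4 h, and 3 plain explanations were examined. Control arrays shared by the choice of genes and the comparison gave 0% lowered in simulations, against 45.9% observed. With no change put in, few genes can pass the adjustment, so that share cannot decide. The lowest simulated median change of induced genes was -0.03, against -0.52 observed, which argues against shared arrays as the main source. With genes taken from the mean of both treatments 37.5% were lower. For 1 weaker response of all genes, 33.2% of 518 induced genes departed from the median attenuation of 24.3%. Of the 458 below the top of the scale 32.1% did. Folds of genes dim at 0 h are understated, so a shared attenuation stays open. For 1 delay of all genes, 34.2% departed from the best mixture of control levels at 2 h and 4 h (34.5% of the 458). No array lies between 2 h and 4 h. A gene whose level bends there departs under 1 delay too, so this also stays open. An effect of the inhibitor that differs from gene to gene may account for the pattern and remains a hypothesis, as it was found and tested on the same arrays.

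Arrays of replicate 1 stood apart from those of replicates 2 and 3 in both treatments. An LPS response further along in replicate 1 may contribute: its deviations at 2 h followed the LPS change with slopes of 0.201 in control and 0.177 in treated cells, against 0.0467 and 0.0799 before LPS and 0.0446 and 0.00306 at 4 h. One offset of replicate 1 at every time cannot be told apart from it, because the deviations at 0 h and 2 h correlated at up to 0.483, less than the 0.783 between treatments at 2 h but above 0. No batch is given in the labels, and no other explanation was tested.

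The 6 arrays of a comparison have 10 splits, the real one included, too few for a share under 0.05. For inhibitor against control the real split called 107 genes at 1 h, 569 at 2 h and 1874 at 4 h and the highest other split 9, 6 and 0, and the 1 split of 10 that reached the real count was the real one. Before LPS the real split called 13, and 2 of 10 splits, the real one included, reached that count. The highest called 62 genes, several times the real count, which points to a structure of the samples, and it set control replicates 1 and 2 with inhibitor replicate 1 against the rest (45 genes with the replicate number as a block, against 23 for the real split). For LPS the real and highest other counts were 263 and 0, 2070 and 0, and 4313 and 0 in control cells and 263 and 5, 1468 and 0, and 3807 and 0 in treated cells. The shares of induced genes lowered were 25.6% against 7.14% at 1 h, 38.5% against 1.21% at 2 h and 45.9% against 0% at 4 h, and the timing difference 26.2 against 0. At 4 h no other split called a gene, so its share and timing difference could only be 0 and add nothing to the gene counts. The other splits also mix the treatments, so an inhibitor effect widens their spread and lowers their counts. Lists called numbered 2 against 5 at 0 h (7 of 10 splits as many), 10 against 12 at 1 h (4 of 10), 10 against 10 at 2 h (2 of 10) and 9 against 8 at 4 h (1 of 10). Since the numbers pair the samples, the real split was also set against the 3 other splits that part all 3 pairs, the highest of which called 0 genes in each comparison of inhibitor with control, while the remaining splits keep some pairs together. Those 3 splits called up to 2, 10, 10 and 8 lists in turn, as many as the real split at 0, 1 and 2 h.

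For the difference of the inhibitor effect from 0 h, 18 of 100 splits drawn within both times gave as many genes at 1 h (2 genes, highest other 96), 14 at 2 h (72, highest other 440) and 13 at 4 h (658, highest other 1225), so chance is not excluded by this count. Most splits that reached the real count kept the real grouping at the later time (14 of 17, 13 of 13 and 12 of 12), and the highest of those that did not called 4, 3 and 0 genes.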

How the results depend on the processing

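The floor at the 95th percentile, the filter on all 24 arrays, background subtraction, centring on housekeeping genes, cyclic loess and leaving out all arrays of 1 replicate number were chosen after the data were seen, and the other alternatives were planned. Background correction from raw signals, median scaling, detection p-value filters and a slide block were planned and not run, because the raw signals could not be matched to samples. Every probe as its own feature, an intensity trend with robust variances, the floor at the 95th percentile and induced genes at a log2 change of at least 2 left the summary counts, shares and list totals they apply to within 1.5 times and on the same side of the test. Of 291 comparisons of named genes 232 were called, none reversed under any of 39 settings, 62 lost the call without some 1 array and 170 kept it. Folds of dim genes are limited by signal over background, as nothing was subtracted. Unless a cause is given, the cause was not tested.

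With the replicate number as a block, the genes called higher at 0 h numbered 23, those lower and higher 141 and 66 at 1 h, 637 and 516 at 2 h and 1262 and 1613 at 4 h. LPS calls in control cells were 518 at 1 h and 3199 at 2 h, and in treated cells 557 and 2442. Differences from 0 h were 13, 246 and 1424, the shares of induced genes lowered 37.0%, 54.9% and 57.7%, and the genes lower at both 2 h and 4 h 445. Besides the 7 comparisons of named genes that gained a call under the block and the list calls given with the results, it changed no other call of a named gene or list, and it ended 0 calls of named genes.

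Array weights, which gave replicate 1 weights of 0.348 to 0.502 and whose estimation stopped before its convergence tolerance was met, called 13 genes lower and 35 higher at 0 h, 161 lower at 1 h, and 857 lower and 790 higher at 2 h. LPS calls became 1132 and 4273 at 1 h and 2 h in control cells and 723 and 2726 in treated cells, differences from 0 h 62, 728 and 1464, shares 37.4%, 60.2% and 50.9%, and the overlap of lower genes at 2 h and 4 h 409.

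Fitting only the arrays compared, which leaves fewer arrays to estimate the spread, gave 6 genes higher at 0 h, 34 lower at 1 h, and 172 lower and 95 higher at 2 h. LPS calls at 1 h were 143 in control and 140 in treated cells, and 864 at 2 h in treated cells. Differences from 0 h were 0 at 1 h and 18 at 2 h, shares 13.1% at 1 h and 25.6% at 2 h, and the overlap 129. Limma's 0 at 1 h stood beside 175 genes at an unadjusted p under 0.05.

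At an adjusted p under 0.01, a stricter call, 36 genes were lower and 25 higher at 1 h, 179 and 121 at 2 h and 521 and 603 at 4 h. LPS calls were 154 and 1362 at 1 h and 2 h in control cells and 141 and 880 in treated cells. Differences from 0 h were 18 at 2 h and 267 at 4 h, shares 16.8%, 27.0% and 35.0%, and the overlap 116.

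Keeping only genes above the floor on all 24 arrays, which tests fewer genes and removes those off before LPS, gave 7 higher at 0 h, 36 lower and 28 higher at 1 h, 170 LPS calls in treated cells at 1 h, 0 differences from 0 h at 1 h (104 at limma's unadjusted p under 0.05) and 20 at 2 h, shares of 32.9% at 2 h and 37.9% at 4 h, and an overlap of 149. With no filter on dim probes the 4 h share was 42.0%. Background subtraction gave 4 differences from 0 h at 1 h. Centring on housekeeping genes called 1382 lower and 566 higher at 4 h with a share of 54.3%, since it moves all values of an array alike, and cyclic loess gave a 4 h share of 50.1%. Induced genes taken from the mean of both treatments, which does not choose genes on control arrays alone, gave shares of 12.8%, 30.5% and 37.5%. With an estimated correlation 6 list tests were called in place of 31. The timing difference stayed on the same side of the test but fell from 26.2 to 15.8, 15.4 and 15.3 percentage points under settings given with the result.

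Leaving out each array in turn, or all arrays of 1 replicate number, gave the ranges that follow, and fewer arrays widen the error. Genes lower and higher with the inhibitor numbered 0 to 1 and 7 to 15 at 0 h, 3 to 90 and 6 to 51 at 1 h, 80 to 482 and 59 to 221 at 2 h, and 349 to 997 and 364 to 1121 at 4 h. LPS calls in control cells were 72 to 290, 975 to 2116 and 3031 to 4472 at 1, 2 and 4 h, and in treated cells 47 to 436, 506 to 1804 and 2336 to 4179. Differences from 0 h were 0 (without replicate 3, with 69 at limma's unadjusted p under 0.05) to 14, 5 to 225 and 72 to 1035. Shares of induced genes lowered were 1.82% to 34.8%, 15.2% to 52.2% and 26.9% to 56.6%, the timing difference 8.97 to 30.4, the list tests called 30 to 36 (p53 targets passed as lower at 0 h without replicate 1, at 0.0145), and the overlap of genes lower at 2 h and 4 h 57 to 290. Over all alternatives, computed for the next overlaps after the data were seen, genes lower and higher at both 1 h and 2 h numbered 2 to 109 and 3 to 58, those at both 1 h and 4 h 1 to 64 and 3 to 52, and those higher at both 2 h and 4 h 51 to 437, each lowest without replicate 3. The timing difference no longer passed without replicate 2, and Fisher's exact p over its alternatives ran from 3.68e-08 to 0.0905.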

Other observations

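The test of genes that fell with LPS was written before its result was seen. Its values under other scalings, and the genes and families described with it, were chosen after the results were seen.

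Some genes that the naming rule took remain to be given. Slc7a11, the cystine transporter gene, fell with the inhibitor by 1.32 ± 0.29 at 2 h (adjusted p = 0.00549) and fell by 1.13 ± 0.29 at 4 h (adjusted p = 0.00661). The death receptor gene Fas fell by 0.94 ± 0.14 at 2 h and fell by 0.76 ± 0.14 at 4 h. Fcgr2b, the inhibitory receptor for immunoglobulin G, changed by -0.64 ± 0.14 and -0.98 ± 0.14. At 4 h Nlrp3, the inflammasome sensor gene (-0.99 ± 0.24), Fscn1, which encodes an actin-bundling protein (-0.96 ± 0.20), the signalling feedback gene Socs1 (-0.78 ± 0.17) and Nr1h3, which encodes the oxysterol receptor LXR alpha (-0.71 ± 0.14), were also lower, and Zfp36, which encodes an RNA-destabilising protein, was higher (1.06 ± 0.28, adjusted p = 0.00842). All of these were called by limma with 3 arrays per group.

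Histone genes of the list, which lacks H2ac6 and H4c18, were counted by family. Called higher at 0, 1, 2 and 4 h were 1, 7, 8 and 9 of 10 H2B genes and 4, 6, 7 and 7 of 8 H3 genes. Of 7 H4 genes these were 5, 5, 5 and 7, and of 15 H2A genes 1, 1, 2 and 4. The H2A medians at 2 h and 4 h were -0.01 each, and -0.07 and -0.15 after centring on housekeeping genes or -0.07 and -0.13 after cyclic loess. The differences between families were not tested.

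One hypothesis was that the inhibitor dampens the falls caused by LPS as well as the rises, in which case genes that fell with LPS would be called higher more often relative to lower than genes LPS did not change. Of 371 genes that fell at 4 h by a log2 change of at least 1 over the mean of both treatments, 51 (13.7%) were called higher and 41 (11.1%) lower with the inhibitor, or 1.24 higher per lower. Of 3101 genes not called for that mean, 413 (13.3%) were higher and 193 (6.22%) lower, or 2.14 per lower (two-sided Fisher's exact test across genes, p = 0.018). The smaller ratio came from more genes called lower, while the shares called higher lay close together, so the ratio was the wrong quantity to decide on and the hypothesis is left open. After centring on housekeeping genes 9.17% of the fallen genes were higher and 21.8% lower, against 6.73% and 9.84% of the genes not called (ratios 0.42 and 0.684, Fisher's exact p = 0.0926). After cyclic loess these were 10.7% and 18%, against 9.36% and 7.56% (ratios 0.592 and 1.24, Fisher's exact p = 0.00352). Genes are not independent replicates in this test.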
